A study of Drosophila melanogaster with 4 samples.

How the data were processed

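RNA was measured in 4 ovary samples, 2 labelled *bam* RNAi and 2 labelled *Nipped-A* RNAi, all driven in the germline with nosGAL4 in the presence of UAS-Dcr2. Libraries were directional and poly(A)-selected, per the labels' protocols. The authors deposited 1 table of raw counts per gene and library. Reads were aligned to dm6 with HISAT2 2.1.0, counted with featureCounts 1.6.0.4 and analysed with edgeR 3.16.5, per the submitters' processing notes. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap another gene, lie antisense to one or have near-identical copies therefore have uncertain counts. Each table listed 17023 FlyBase gene identifiers, and 16647 matched a symbol and position in the reference annotation (Ensembl gene models on the dm6 coordinates); the other 376 stayed in the tests without a name. Of the 10245 genes tested 213 had no symbol, and of the genes called 43 had none.

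The totals were 33844807, 23866988, 47825006 and 21193517 counts for *bam* RNAi 1 and 2 and *Nipped-A* RNAi 1 and 2. The 20 most abundant genes took 10.3%, 10.2%, 7.53% and 7.74% of them. Genes were kept with filterByExpr and scaled with TMM in edgeR 4.0.16 (R 4.3.3), with factors of 0.980, 0.983, 1.03 and 1.01, and 6778 genes were not tested. The groups were compared with the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) on the counts, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values are scaled with the TMM factors. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. A fold against a group at 0 counts in both libraries is a lower bound computed with 3 counts over that group, which covers counting error only. The Pearson correlation of log2 CPM was 0.972 between the *bam* RNAi libraries, 0.954 between the *Nipped-A* RNAi libraries and 0.830 to 0.898 between groups. The biological coefficient of variation was 0.332, and 10.2% of genes differed by over 2-fold between the *bam* RNAi libraries and 13.7% between the *Nipped-A* RNAi libraries. The chi-square per gene, a measure of spread beyond counting error that grows with depth, was 21.4 for the *bam* RNAi pair. It was 226 for the *Nipped-A* RNAi pair (genes with at least 10 counts over a pair).

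The groups, tests, 28 gene lists and the rule for named genes were fixed before the data were examined. Named genes are the 2 targets; the 12 genes with a symbol and the largest log2 fold change in each direction among those past the threshold, with both libraries of a group beyond both of the other and a mean of at least 4 CPM; and for each list up to 4 called members with the smallest adjusted p, or the most abundant member where none was called. Genes named outside this rule, to complete small counts or describe a cluster, were chosen after their values were seen: *brat*, *mei-P26*, *plu*, *png*, *grk*, *ovo*, *Cp38*, *Cp36*, *Cp7Fb*, *Cp7Fc*, *Cp18*, *Cp15*, *Cp16*, *Cp19*, *mirr*, *srp*, *Lsd-1*, *Obp99b*, *Def*, *dom*, *MrgBP*, *Tip60* and those of the closing observations. Lists were tested with limma 3.58.1 camera, two-sided, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 28 lists, with an estimated correlation and fry beside it. With an estimated correlation 0 of the 28 lists passed, and with fry 0. The smallest unadjusted camera p with an estimated correlation was 0.115, for oxidative phosphorylation. The gut list, with all 10 members higher, had 0.202. With 2 libraries per group this version has little power, and most lists share its adjusted p = 0.812. That value therefore does not decide for or against any single list. The smallest adjusted p of fry was 0.0774. List members without a match in the files by symbol were *vas*, *lola*, *Med*, *br*, *wupA*, *corolla*, *vilya*, *solo*, *Nplp2*, *para*, *Mcm3*, *Orc1*, *Drs* and *boot*. Chromosome arms were tested with two-sided Fisher exact tests.

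The steps were tested on simulated counts with the means and library sizes of these samples and 200 changed genes in each of 10 draws (9961 to 10002 genes). At 2-fold 18.7% of the changed genes were recovered and at 4-fold 74.8%, with median fitted folds of 2.02 and 3.97. Of 1077 calls 142 were false, or 13.2%, above the nominal 5%. The changed genes were drawn from the more abundant ones, and each gene kept the dispersion fitted in the real data. In the real data 2004 of 10245 genes were called, a far larger share than was changed in the simulation. Recovery and the false share depend on that share, so these rates do not carry over to the real calls. Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, robust moderation, other filters, the replicate number as a block and each library left out in turn. Others were added after seeing the data: an estimated correlation together with other settings, calls restricted to genes whose *Nipped-A* RNAi libraries lay within 2-fold of one another (0.1 CPM added), and removal of the trend with gene length. For the latter, a lowess curve (span 0.3) of each library's log2 CPM deviations on log2 exonic length entered the edgeR fit as an offset. On simulated counts with a length trend the Spearman correlation of fold change and length went from 0.436 to 0.00829. In the real data it went from 0.243 to −0.040, slightly past 0. The simulated trend was the same in both libraries of a group, whereas the real one also lay between the *bam* RNAi libraries (0.249).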

Results

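Poly(A) RNA was sequenced from *Drosophila melanogaster* ovaries dissected 2 to 3 days after eclosion. Each fly carried nosGAL4, which drives expression in germ cells, together with UAS-Dcr2, which strengthens RNA interference. The first genotype carried an RNAi hairpin against *bam* (bag of marbles), the differentiation factor that germline stem cell daughters need to form a cyst. The second carried a hairpin against *Nipped-A*, the large scaffold protein shared by the Tip60 and SAGA histone acetyltransferase complexes. There were 2 libraries per genotype and no untreated group, so each knockdown was read against the other and neither against a wild-type level. The count tables summed to 33844807 and 23866988 counts in the libraries labelled *bam* RNAi 1 and 2, and to 47825006 and 21193517 in the libraries labelled *Nipped-A* RNAi 1 and 2. The deposited tables listed 17023 genes, of which 10245 had enough counts to be tested. All fold changes are the libraries labelled *Nipped-A* RNAi over the libraries labelled *bam* RNAi, with n = 2 per group. The labels do not say whether the libraries came from separate pools of flies, so the p-values measure the spread between these samples, which might be technical only.

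The first comparison asks whether each targeted transcript was lower in the libraries labelled as its knockdown. *bam* was 4.10-fold higher in the libraries labelled *Nipped-A* RNAi, which places it lower in the libraries labelled *bam* RNAi. *Nipped-A* itself was 1.62-fold higher in the libraries labelled *Nipped-A* RNAi, which is the opposite of its label. Every direction given from here on therefore refers to the labels of the libraries and not to a reduced *Nipped-A* transcript. *bam* (FBgn0000158, dm6 chromosome 3R, 25243039 to 25245109) had 4.70 and 6.52 CPM (counts scaled to library size) in the libraries labelled *bam* RNAi and 29.0 and 16.9 CPM in those labelled *Nipped-A* RNAi, or 5.61 ± 1.29 against 22.9 ± 8.60 (mean ± SD, n = 2). Its log2 fold change was 2.03 ± 0.38 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0254). *Nipped-A* (FBgn0053554, chromosome 2R, 5177965 to 5251022) had 287 and 247 CPM against 430 and 439 CPM, or 267 ± 28.4 against 434 ± 6.16. Its log2 fold change was 0.70 ± 0.14 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0287). Fold changes in these libraries rose with gene length, and *Nipped-A* has 11519 exonic bases; with that trend removed its log2 fold change was 0.31 ± 0.12 (edgeR, Benjamini-Hochberg adjusted p = 0.130), and the call ended because the fold change shrank. Upper-quartile scaling ended it too, at 0.49 (adjusted p = 0.0524), and without *bam* RNAi library 1 or 2 neither target was called (adjusted p = 0.175 and 0.202 for *bam*, 0.172 and 0.307 for *Nipped-A*).

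The second comparison asks which transcripts differ between the ovary samples of the germline knockdowns. Of the listed maternal transcripts loaded into the oocyte 13 of 16 rose in the libraries labelled *Nipped-A* RNAi, as did 12 of 21 yolk and eggshell genes and the cyclins *CycA* and *CycB*. The cystoblast gene *bgcn*, the meiotic genes *sunn*, *ord* and *cona*, and 65 of 83 cytoplasmic ribosomal protein genes, 49 of 66 oxidative phosphorylation genes and 11 of 15 muscle sheath genes fell there. The 10 digestive enzyme genes of the gut list, each below a mean of 1 CPM in the libraries labelled *bam* RNAi, all rose. Carried-over gut and gut genes switched on in ovarian cells cannot be told apart. The rises counted below, which include these genes, are therefore not all known to be ovarian. The lists of maternal, yolk and eggshell, cytoplasmic ribosomal protein, oxidative phosphorylation, muscle sheath and gut genes passed camera with a preset correlation but not with an estimated one (adjusted p = 0.812 with an estimated correlation). With 2 libraries per group the estimated version has little power, and most lists share that value, so it does not decide on any of them. In all, 2004 of 10245 genes changed (edgeR quasi-likelihood test, Benjamini-Hochberg threshold 0.05), with 1153 higher and 851 lower in the libraries labelled *Nipped-A* RNAi. Of these, 737 were higher and 460 lower by at least 2-fold, and 294 were higher and 89 lower by at least 8-fold. Upper-quartile scaling, which shifted the median of all genes by −0.21 on the log2 scale, turned the balance to 853 higher and 1556 lower, and DESeq2 called 3620 genes, 2172 higher and 1448 lower. Both groups were fully separated at 68.9% of the tested genes, where chance alone gives 33.3%. edgeR called 0 genes without *bam* RNAi library 1 or 2, with 2373 and 1837 genes at an unadjusted p below 0.05 and 1583 and 1148 called by DESeq2. Without *Nipped-A* RNAi library 1 or 2 it called 3886 and 4215.

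Rises were ranked by fitted fold change among called genes with a symbol and a mean of at least 4 CPM. The 12 largest had 0 counts in both libraries labelled *bam* RNAi. Folds for these genes are lower bounds against a floor of 3 counts over the group. By those bounds they do not rank above genes that had counts there, such as *betaTry* at 1913-fold. *CG8661* (chromosome X) was at least 1350.4-fold higher, at 53.4 and 113 CPM in the libraries labelled *Nipped-A* RNAi 1 and 2. The serine protease gene *Jon65Aii* was at least 1248-fold higher, at 18.5 and 176 CPM, and the lysozyme gene *LysE* at least 355-fold, at 8.77 and 41.8 CPM. *CG9682* was at least 514-fold higher and was nearly even between the libraries, at 25.5 and 31.2 CPM. *CG14120*, *Diedel3*, *CG42397*, *CG4377*, *Fst*, *CG31446*, *Ser6* and *CG10912* made up the rest, each at least 252-fold higher over the 2 libraries together. In libraries 1 and 2 *CG14120* had 5.19 and 130 CPM, *Diedel3* 8.20 and 83.7, *Fst* 4.74 and 50.8 and *Ser6* 4.25 and 34.3. The bounds of these genes therefore depend on library 2. Of the 12, 8 lost their call under robust moderation and the same 8 under limma-voom, among them *Jon65Aii* and *LysE*, while *CG8661*, *CG9682*, *CG31446* and *CG10912* kept it under both. *CG14120* was also not called with the length trend removed. The 12 largest falls were taken by the same rule, with the same minimum mean of 4 CPM. *Fbp2* among them went from 31.2 and 24.0 CPM in the libraries labelled *bam* RNAi to 0.224 and 0 CPM, a log2 fold change of −7.58 ± 0.86. *Fbp1*, the receptor for larval serum proteins, changed by −7.20 ± 1.00, and the serum protein genes *Lsp1alpha* and *Lsp1gamma* by −5.30 and −5.27. The flight muscle actin *Act88F* went from 86.4 and 81.0 CPM to 0.916 and 0.187 CPM. *SPH93*, *CG6938*, *CG34215*, *NANS*, *CG5402*, *Nplp4* and the cuticle gene *Cpr49Ae* completed the 12, between −5.84 and −4.23 on the log2 scale. *Fbp1* and *Lsp1alpha* lost their call under robust moderation.

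Germline genes moved in different directions. Of the 16 oocyte and maternal transcripts tested, 13 rose (14 adjusted over the list alone), with a median log2 fold change of 1.76. *osk*, which organises the germ plasm, rose 8.32-fold from 82.8 and 82.9 CPM to 923 and 455 CPM (3.06 ± 0.36). *zld*, the activator of the zygotic genome, rose 4.95-fold, the anterior determinant *bcd* 3.65-fold and the maternal thioredoxin *dhd* 5.26-fold. The members not called were *plu*, *png* and *grk*, the last at −0.27 ± 0.33. The list passed limma camera with a preset correlation (Benjamini-Hochberg adjusted p = 6.40e-06), and adjusted p = 0.812 with an estimated correlation. Among 16 genes of cystoblast differentiation and cyst formation, 6 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.59; camera adjusted p = 0.181). Under upper-quartile scaling 6 rose and 2 fell, and with the length trend removed 4 rose and 4 fell, with a median of 0.26. The gene that fell in the main setting was *bgcn*, which encodes the binding partner of Bam: it had 113 and 106 CPM in the libraries labelled *bam* RNAi and 14.2 and 20.7 CPM in the others (−2.66 ± 0.24). *otu* (2.00), *orb* (1.83) and *bru1* (1.85), which act in cyst growth and translational control, rose, as did *brat*, *mei-P26* and *bam*.

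Of 14 genes of meiosis and the synaptonemal complex, 3 fell and 1 rose (3 and 1 adjusted over the list alone). The cohesin-related genes *sunn* (−2.81 ± 0.24) and *ord* (−1.90 ± 0.26) and the central-region gene *cona* (−2.67 ± 0.30) fell, and *mtrm*, an inhibitor of Polo kinase in the oocyte, rose 5.42-fold. This list had a median of 0.17 (−0.05 under upper-quartile scaling, −0.26 without *Nipped-A* RNAi 1), a mean of −0.20 and a downward camera direction (adjusted p = 0.724). Among 14 germ cell markers, *osk*, *tud*, *nanos* and *ovo* rose and *qin* fell (5 and 2 adjusted over the list alone; 3 and 3 under upper-quartile scaling or with the length trend removed); the median was −0.14 (0.14 without *Nipped-A* RNAi 2), the mean 0.23 and the camera direction upward (adjusted p = 0.924). Of 15 genes of stem cell self-renewal and the BMP response, 4 rose (5 adjusted over the list alone; camera adjusted p = 0.0703): *Smurf* (1.00), *shn* (0.81), *nanos* (1.38) and *pum* (0.65). Without *Nipped-A* RNAi 2 this list passed camera (adjusted p = 0.0102, and adjusted p = 0.832 with an estimated correlation). The calls of *shn* and *pum* ended with the length trend removed, *pum* also under upper-quartile scaling, and that of *nanos* under robust moderation and limma-voom. In the piRNA pathway, 6 of 26 genes fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.326). The rise was of *del* (1.18 ± 0.13), a subunit of the complex that licenses piRNA cluster transcription, while its partner *cuff* fell (−1.54 ± 0.28), along with *piwi* (−0.77) and the somatic factor *fs(1)Yb* (−1.45).

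**Figure D1:**
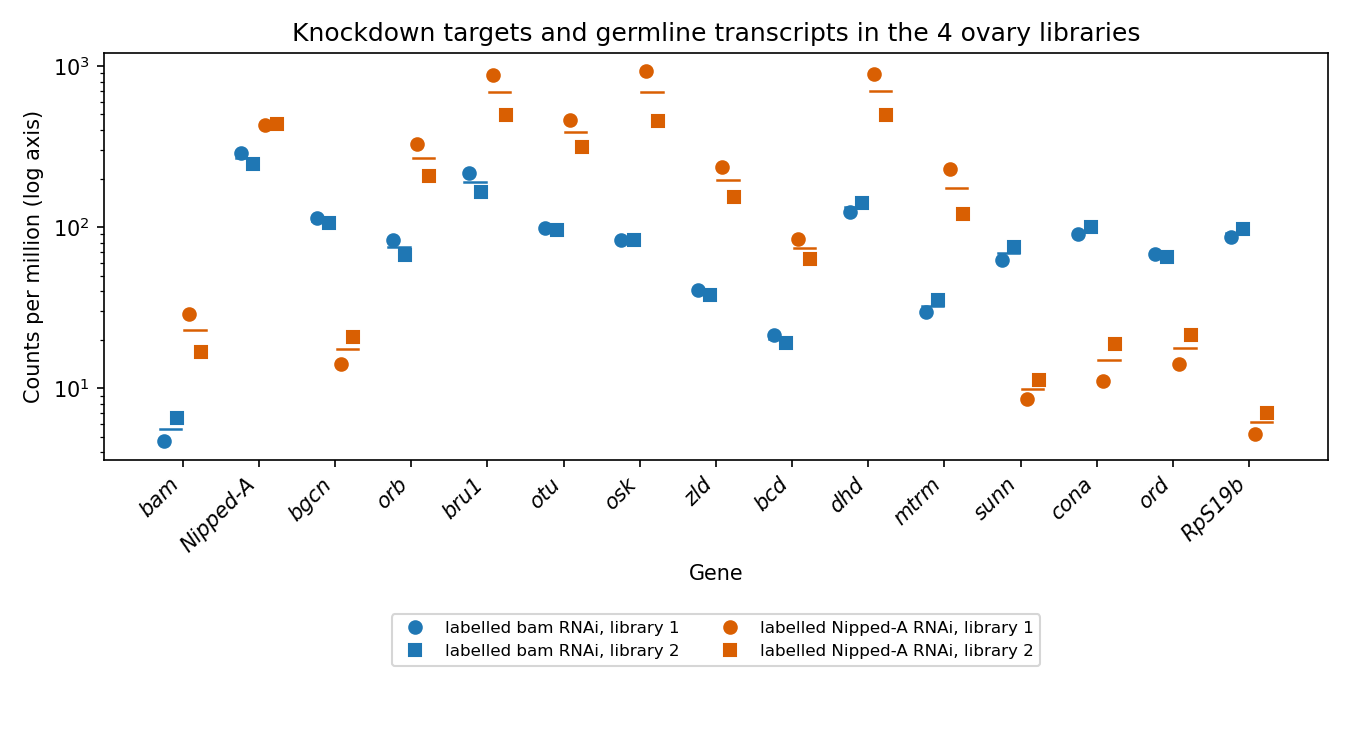
CPM (log axis) of the 2 targeted genes and 13 germline genes in each of the 4 libraries, with circles for library 1, squares for library 2 and a short line at each group mean. Both libraries labelled *Nipped-A* RNAi lie above both labelled *bam* RNAi for *bam*, *Nipped-A* and *osk*, and below them for *bgcn*, *sunn*, *cona*, *ord* and *RpS19b*.

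Among 21 yolk, vitelline membrane and eggshell genes, 12 rose and 1 fell (15 and 2 adjusted over the list alone; median 0.93; camera adjusted p = 0.000359, and adjusted p = 0.812 with an estimated correlation). The grouping of chorion genes by chromosome was made after their values were seen and was not tested. On the X chromosome *Cp7Fa* rose from 1.15 and 1.19 CPM to 84.9 and 46.6 CPM (5.81 ± 0.40), and *Cp38* from 19.5 and 23.7 CPM to 2814 and 686 CPM. *Cp36* went from 16.3 and 20.5 CPM to 1873 and 414 CPM, *Cp7Fb* from 1.87 and 4.22 to 351 and 33.5 CPM, and *Cp7Fc* from 1.42 and 2.69 to 233 and 22.9 CPM. The levels of *Cp38*, *Cp36*, *Cp7Fb* and *Cp7Fc* were higher in *Nipped-A* RNAi library 1 than in library 2, so the sizes of these rises depend on library 1. On chromosome 3L *Cp18* fell (−0.93), a call that ended under RLE scaling, library size alone and with the length trend removed, and *Cp15* (−0.09), *Cp16* (−0.75) and *Cp19* (0.34) were not called. The eggshell gene *dec* rose 2.91-fold, the vitelline membrane gene *Vm32E* 3.78-fold and the yolk protein gene *Yp3* 2.47-fold. Of 13 follicle cell genes, 3 rose and 2 fell (6 and 4 adjusted over the list alone; median 0.48; camera adjusted p = 0.711). *yellow-g2* and *yellow-g*, which are active in late follicle cells, rose by 7.55 ± 0.86 and 5.32 ± 0.67, and *peb* by 1.74, while *eya* (−1.01) and *mirr* (−1.09) fell. In *Nipped-A* RNAi libraries 1 and 2 *yellow-g2* had 246 and 61.3 CPM and *yellow-g* 260 and 75.4 CPM. The sizes of the rises of *yellow-g2* and *yellow-g* thus depend on library 1 as well. The call of *yellow-g2* ended under limma-voom.

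Genes of other ovarian and non-ovarian cells also differed. Of 15 muscle sheath genes 11 fell (12 adjusted over the list alone), with a median of −1.43 (camera adjusted p = 6.81e-06, and adjusted p = 0.812 with an estimated correlation). The muscle actin *Act57B* fell by 2.30 on the log2 scale, from 11120 and 11655 CPM to 2272 and 2364 CPM, with *Mlc1* at −1.96 and the troponin gene *TpnC73F* at −1.89. Among 9 hemocyte genes 4 fell and *srp* rose (6 and 2 adjusted over the list alone; median −0.89; camera adjusted p = 0.0575). The call of *srp* ended under upper-quartile scaling, with 6 falls, and with the length trend removed, with 5. The falls were of the collagen IV genes *Col4a1* (−1.73 ± 0.14) and *vkg* (−1.66 ± 0.13), the phagocytosis receptor *NimC1* (−1.78) and *Pxn* (−0.89). In the 14 cap and escort cell genes of the germarium the single call was the BMP ligand *dpp* (−1.10 ± 0.19; 1 adjusted over the list alone; median −0.32; camera adjusted p = 0.181). With the length trend removed both the hemocyte and the cap and escort lists passed camera, at adjusted p = 0.00624 and 0.00995, and adjusted p = 0.848 for each with an estimated correlation. The hemocyte list also passed under RLE scaling, library size alone and without *bam* RNAi 2 (adjusted p = 0.0462, 0.0458 and 0.0336; adjusted p = 0.810, 0.822 and 0.880 with an estimated correlation), and the cap and escort list without *Nipped-A* RNAi 2 (adjusted p = 0.0329; adjusted p = 0.837 with an estimated correlation). Of 10 fat body genes 2 rose and 4 fell (2 and 4 adjusted over the list alone; 1 and 3 with the length trend removed; camera adjusted p = 0.274): *apolpp* (1.49) and *Lsd-1* (0.92) rose, and *Fbp1*, *Fbp2*, *Lsp1gamma* and *Obp99b* (−3.77) fell. The fat body median was −0.49, but −1.71 without *Nipped-A* RNAi 1, where the list passed (adjusted p = 0.00546; adjusted p = 0.758 with an estimated correlation), and 0.10 without *Nipped-A* RNAi 2.

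All 10 gut genes tested rose (10 adjusted over the list alone), with a median of 8.89, or 8.67 with genes at 0 set at their bound (camera adjusted p = 9.48e-07, and adjusted p = 0.812 with an estimated correlation). The protease gene *Jon65Aiv* went from 0.874 and 0.938 CPM to 358 and 756 CPM, *Jon65Aiii* from 1.15 and 0.682 to 214 and 494 CPM, and the trypsin gene *alphaTry* from 0.874 and 1.07 to 187 and 669 CPM. *betaTry* had 0.121 and 0 CPM against 59.0 and 223 CPM. All 10 were higher in *Nipped-A* RNAi library 2 than in library 1, by a median of 2.49 on the log2 scale, while all 16 maternal transcripts were lower in library 2, by a median of −0.67. These proteases and amylases have near-identical copies among which reads could be divided, so single members are uncertain, and the calls of *alphaTry* and *betaTry* ended under limma-voom. Of 16 immune genes 4 fell and 1 rose (4 and 2 adjusted over the list alone); the median was 0.57 (−1.31 with a 1 CPM filter, −0.66 without *Nipped-A* RNAi 1) and the camera direction downward (adjusted p = 0.724). The antimicrobial peptide genes *DptA* (−6.63 ± 0.60), *DptB* (−5.42 ± 1.09), *AttC* (−4.05 ± 0.60) and *Def* (−1.30) fell, and *PGRP-SC1a*, an amidase, was at least 108-fold higher. Among 9 testis genes *aly* fell and was 4.01-fold lower (0 adjusted over the list alone by edgeR, 2 at an unadjusted p below 0.05 and 1 by DESeq2; camera adjusted p = 0.167), a call that ended with the length trend removed. Among 11 neuronal genes *VGlut* fell (−5.24; 1 adjusted over the list alone); the median was 0.11 (−0.09 under upper-quartile scaling, −0.06 without *bam* RNAi 2, −0.10 without *Nipped-A* RNAi 2, −0.24 with the length trend removed), the mean −0.33 and the camera adjusted p = 0.902.

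Ribosomal protein, oxidative phosphorylation and proteasome genes that were called fell in the libraries labelled *Nipped-A* RNAi, and for each of these 4 lists, mitochondrial ribosomal proteins included, the adjusted p = 0.812 with an estimated correlation. Of 83 cytoplasmic ribosomal protein genes 65 fell (73 adjusted over the list alone), with a median of −0.79 (camera adjusted p = 1.54e-16). *RpS19b*, a germline paralog, fell most among them, from 87.2 and 97.0 CPM to 5.21 and 7.08 CPM (−3.91 ± 0.24). *RpS5a* (−1.28), *RpL13A* (−1.05) and *RpS19a* (−0.99) fell as well. Of 66 oxidative phosphorylation genes 49 fell (59 adjusted over the list alone; median −0.89; camera adjusted p = 4.17e-15), including *SdhD* (−1.23 ± 0.16), *ND-20* (−0.97), *ATPsynO* (−0.91) and *ATPsyngamma*, which was 1.99-fold lower. Of 70 mitochondrial ribosomal protein genes 12 fell (18 adjusted over the list alone; median −0.58; camera adjusted p = 9.48e-10), among them *mRpL2* (−1.23), *mRpS16* (−1.03), *mRpL16* (−0.82) and *mRpS9* (−0.74). Of 37 proteasome genes *Rpt3R* (−1.23) and *Rpn9* (−0.59) fell; edgeR called 0 adjusted over the list alone, with 20 at an unadjusted p below 0.05 and 6 by DESeq2 (median −0.40, and −0.26 without *Nipped-A* RNAi 2; camera adjusted p = 3.09e-05). Under upper-quartile scaling 36 mitochondrial ribosomal protein genes and 21 proteasome genes fell. edgeR called 0 of 12 glycolysis genes, with 4 at an unadjusted p below 0.05 and 4 by DESeq2 (0 adjusted over the list alone; 4 fell under upper-quartile scaling; median −0.24; camera adjusted p = 0.148), and *Gapdh2* had a log2 fold change of −0.09 ± 0.21. Without *Nipped-A* RNAi 1 the glycolysis median was −0.45 and the list passed (adjusted p = 0.00546; adjusted p = 0.758 with an estimated correlation), and without *Nipped-A* RNAi 2 the median was 0.06.

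**Figure D2:**
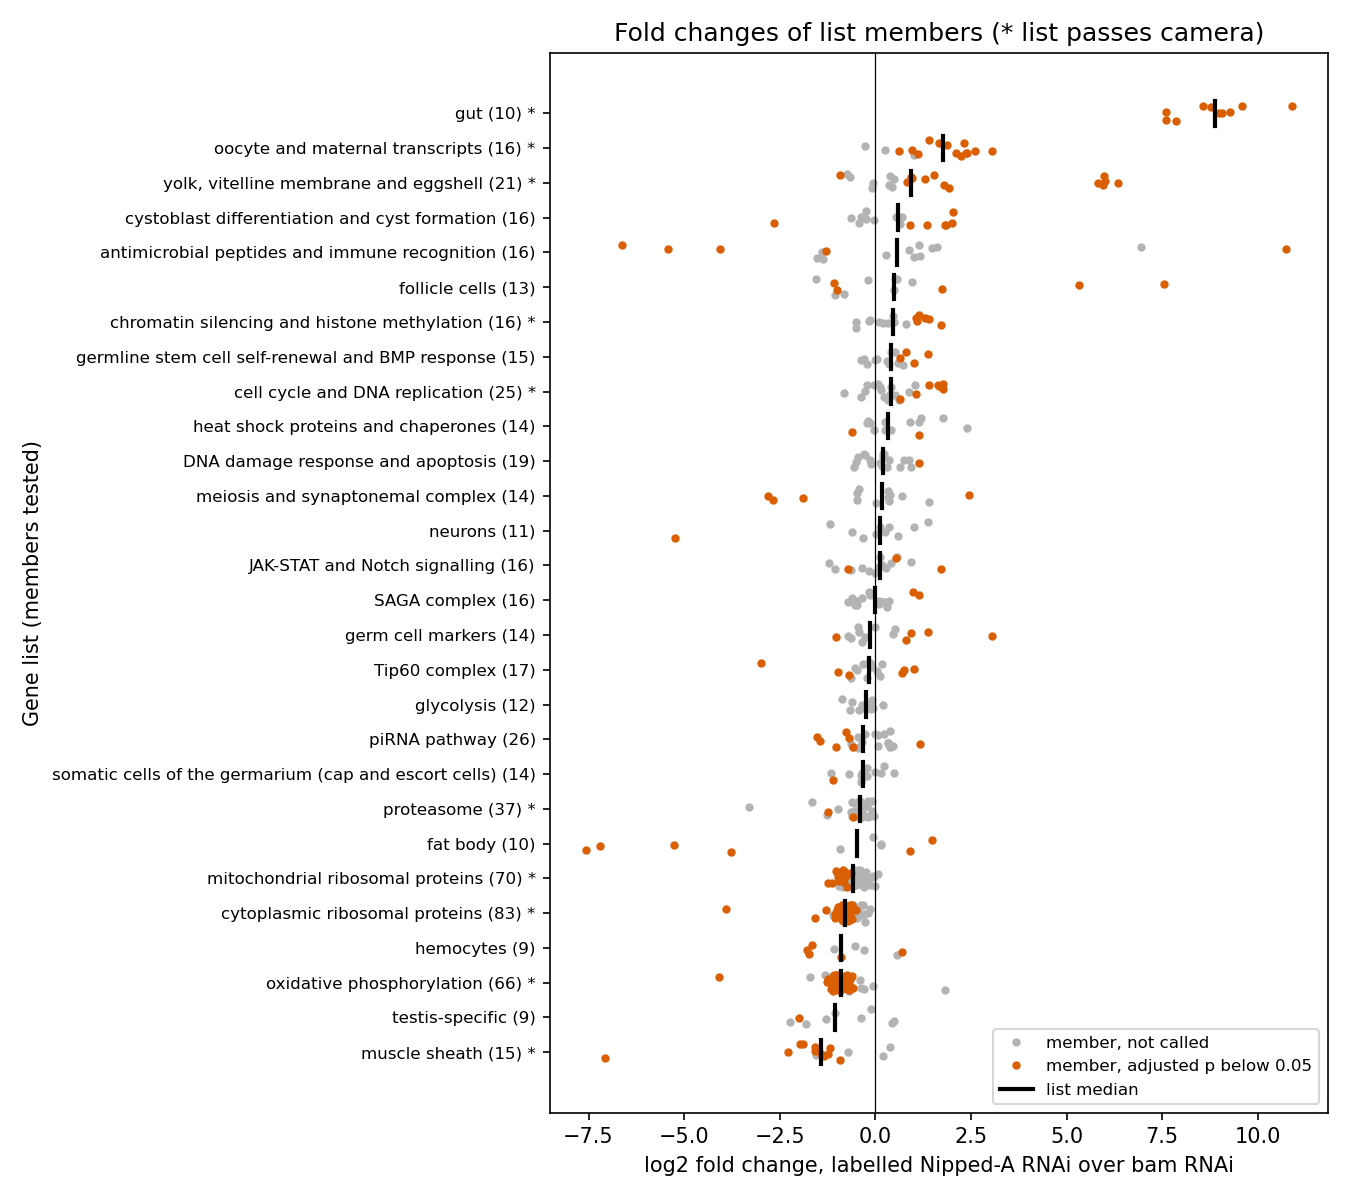
Log2 fold change, libraries labelled *Nipped-A* RNAi over libraries labelled *bam* RNAi, of each member of the fixed gene lists, with each list's median. The gut list lies at a median of 8.89 and the muscle sheath list at −1.43.

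Fold changes rose with gene length, and the median exonic length was 916 bases for cytoplasmic ribosomal proteins, 848.5 for oxidative phosphorylation, 783 for mitochondrial ribosomal proteins and 1393 for the proteasome. Across 10032 genes the log2 fold change had a Spearman correlation of 0.243 with exonic length, and genes are not independent replicates. The shortest 10% of genes (55 to 769 bases) had a median log2 fold change of −0.47 and the longest (5647 to 71820 bases) one of 0.43. The ratio of the 2 libraries labelled *bam* RNAi also had a Spearman correlation with length (0.249), and that of those labelled *Nipped-A* RNAi a weaker one (0.0941). Such correlations rank genes and do not give the size of the fold changes within a pair. With the trend removed, the medians were −0.41 for the cytoplasmic ribosomal proteins (23 falls), −0.53 for oxidative phosphorylation (27), −0.19 for the mitochondrial ribosomal proteins (1) and −0.16 for the proteasome (1). The calls of *ATPsynO*, *mRpS16*, *mRpS9*, *mRpL16* and *Rpn9* ended, and those of *RpS19b*, *RpS5a*, *SdhD* and *mRpL2* did not.

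**Figure D3:**
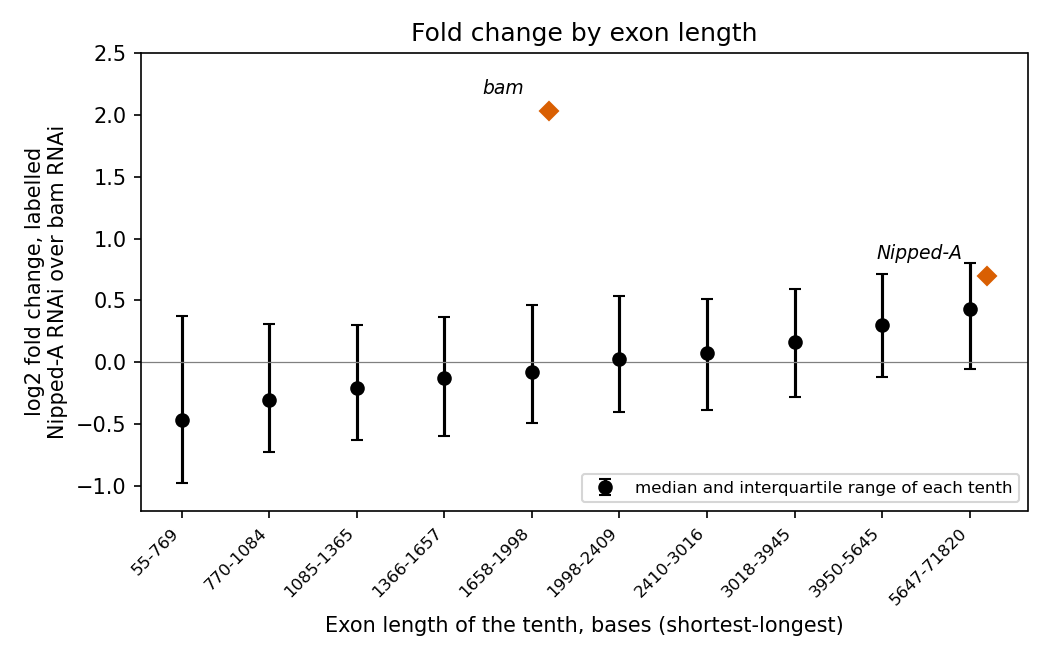
Median and interquartile range of the log2 fold change (libraries labelled *Nipped-A* RNAi over libraries labelled *bam* RNAi) in 10 equal groups of genes ordered by exonic length in bases, with *bam* and *Nipped-A* marked. The medians go from −0.47 in the group of shortest genes to 0.43 in that of the longest.

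Cell cycle and chromatin genes were higher in part. Of 25 cell cycle and replication genes 7 rose (9 adjusted over the list alone; median 0.40; camera adjusted p = 0.0250, and adjusted p = 0.812 with an estimated correlation). The Cdk-activating phosphatases *stg* and *twe* rose 3.39-fold and 3.17-fold, and the cyclins *CycA* and *CycB* 3.09-fold and 3.42-fold. Of 16 genes of chromatin silencing and histone methylation 6 rose (9 rose and 1 fell adjusted over the list alone; median 0.47; camera adjusted p = 0.0277, and adjusted p = 0.812 with an estimated correlation). The histone methyltransferase genes *trx* (1.31 ± 0.13), *G9a* (1.71 ± 0.21), *ash1* (1.40 ± 0.17) and *Set1* (1.09 ± 0.15) were among them. Under upper-quartile scaling 6 of this list rose and 2 fell. With the length trend removed it had a median of 0.33 and no longer passed (adjusted p = 0.120). The camera calls also ended without single libraries: for the cell cycle without *bam* RNAi 1 (adjusted p = 0.0596) or *Nipped-A* RNAi 1 (0.504, with a median of 0.12 against 0.69 without *Nipped-A* RNAi 2), and for chromatin without *bam* RNAi 2 (0.0562) or *Nipped-A* RNAi 1 (0.197).

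The Tip60 complex, to which Nipped-A belongs, did not move as a group in the libraries labelled *Nipped-A* RNAi. Of its 17 genes 3 rose, *E(Pc)* (1.01), *dom* (0.74) and *Nipped-A*, and 3 fell, *Act87E* (−2.99 ± 0.14), *MrgBP* (−0.98) and *rept* (−0.70) (3 and 4 adjusted over the list alone; 1 and 5 under upper-quartile scaling; 2 fell with the length trend removed; median −0.16; camera adjusted p = 0.357). *Act87E* encodes a muscle-type actin with close paralogs among which reads could be divided. The catalytic subunit gene *Tip60* had a log2 fold change of 0.18 ± 0.24. Of 16 SAGA genes *Ada2b* (1.14 ± 0.20) and *Spt20* (1.00) rose (2 adjusted over the list alone; camera adjusted p = 0.981). The calls of *E(Pc)* and *Spt20* ended with the length trend removed. Of 16 JAK-STAT and Notch genes the Notch ligand *Delta* (1.72 ± 0.28) and *Stat92E* (0.53) rose and *fng* (−0.73) fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.769), and the latter 2 were not called with the length trend removed, nor *Stat92E* under upper-quartile scaling or limma-voom. Of 14 heat shock and chaperone genes *Hsp26* (1.14) rose and *Hsp23* (−0.61) fell (1 and 1 adjusted over the list alone; median 0.34; camera adjusted p = 0.418). Without *Nipped-A* RNAi 2 this list passed (median 0.56; adjusted p = 0.0256, and adjusted p = 0.832 with an estimated correlation). Of 19 genes of DNA damage and apoptosis *Corp* (1.14) rose; edgeR called 0 adjusted over the list alone, with 5 at an unadjusted p below 0.05 and 5 by DESeq2 (camera adjusted p = 0.484). The calls of *Hsp23* and *Corp* ended as well, the first with the length trend removed and the second under upper-quartile scaling.

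A further comparison asks whether the changed genes lie on particular chromosome arms. Genes that fell were more frequent on 2L, at 179 of 1800 genes tested (odds ratio 1.28), and less frequent on 3L, at 133 of 1933 (odds ratio 0.780). Genes that rose were less frequent on 2R, at 196 of 2027 (odds ratio 0.817). Each had adjusted p = 0.0479 (two-sided Fisher exact test, Benjamini-Hochberg over 10 tests), and genes are not independent replicates. With calls of at least 2-fold change Fisher's exact test passed 0 of the 10, with 3 at an unadjusted p below 0.05, and with a 1 CPM filter 1 of the 10 passed.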

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

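The restriction to genes with similar *Nipped-A* RNAi libraries, the removal of the length trend, and an estimated correlation combined with another setting were chosen after the data were seen; the other alternatives were planned. Against 2004 changed genes (1153 higher, 851 lower in the libraries labelled *Nipped-A* RNAi; 737 and 460 by at least 2-fold), RLE scaling gave 2055, library size alone 2035, robust moderation 2181, no filter 2512, a 1 CPM filter 2243 and limma-voom 1706, and 0 of the 2004 reversed sign under any of these. Upper-quartile scaling shifted the median of all genes by −0.21 (log2) and gave 1556 lower genes, 794 of them by at least 2-fold, so that 35.4% of calls were higher against 57.5%; *Nipped-A* was then at 0.49 (adjusted p = 0.0524). DESeq2 called 3620 genes, 2172 higher and 1448 lower, with 1110 higher by at least 2-fold and 2003 shared; the cause was not tested. Restricted to similar *Nipped-A* RNAi libraries, 491 genes were higher and 435 lower by at least 2-fold. The restriction thus removed mainly rises, whose *Nipped-A* RNAi libraries differed from one another by over 2-fold. With the length trend removed 1396 genes changed, 1237 of them shared, 1 of the 2004 reversed sign, and *Nipped-A* was at 0.31 (adjusted p = 0.130). Over the fits without a replicate, in which the lone library is assumed to vary like the other group, changed genes ranged from 0 to 4215, higher from 0 to 2511, lower from 0 to 1771, higher by at least 2-fold from 0 to 1089 and lower by at least 2-fold from 0 to 727. The log2 fold change of *bam* ranged from 1.58 to 2.44 and that of *Nipped-A* from 0.60 to 0.83. The 0 calls are edgeR's without *bam* RNAi 1 or 2 (2373 and 1837 at an unadjusted p below 0.05; 1583 and 1148 by DESeq2). Passing gene lists went from 10 to 0 with an estimated correlation, alone or with RLE scaling, library size alone or the length trend removed, and 0 with fry; without a replicate they ranged from 0 (estimated correlation) to 13. Passing chromosome arm tests went from 3 to 0 with 2-fold calls and 1 with the 1 CPM filter. The shared replicate numbers do not pair the libraries as far as the labels say, and the replicate deviations correlated at −0.0756; with the replicate number as a block 1813 genes changed (1124 higher, 689 lower; 1652 shared), with *bam* at 2.00 and *Nipped-A* at 0.70 and 10 lists passing. Of 109 named genes 4 lost their call under upper-quartile scaling, 11 under robust moderation, 13 under limma-voom, 4 under the block (*Rpn9*, *aly*, *Corp* and *Stat92E*) and 15 with the length trend removed; 108 lost it without either *bam* RNAi library. Depth limits genes near the floor, where 62 higher genes had 0 counts in both *bam* RNAi libraries.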

Other observations

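The tests of symbol families, further gut genes, pooled lists and the gene length trend in this part, and the bounds set for each explanation, were chosen only after the results were seen; the fold changes of the targets, the fixed lists and the other scalings were planned. Genes were grouped by the letters that open their symbols, and the 142 families with at least 5 tested members were compared with all other genes by two-sided Fisher exact tests (284 tests, Benjamini-Hochberg). Genes are not independent replicates, and members of a family can vary together from library to library. The p-values of these tests therefore do not measure replication between samples. Besides the ribosomal protein and respiratory families already described, all 5 tested members of the *NimB* family fell in the libraries labelled *Nipped-A* RNAi (adjusted p = 0.000185, Fisher exact). This family encodes secreted relatives of phagocytosis receptors. The hemocyte list members *NimC1* (−1.78), *Col4a1* (−1.73) and *vkg* (−1.66) fell as well. In that list 4 of 9 genes fell and *srp* rose, and it did not pass camera (adjusted p = 0.0575). *NimB2* went from 68.6 and 70.7 CPM to 21.2 and 22.5 CPM (log2 fold change −1.67 ± 0.17), and *NimB5* from 36.2 and 38.2 CPM to 9.77 and 8.86 CPM. *NimB4* (−1.65) and *NimB3* (−2.33) fell, and *NimB1* went from 7.24 and 10.6 CPM to 2.26 and 2.20 CPM. Of the 6 tested *BomS* genes, which encode short peptides induced by Toll signalling, 4 fell (adjusted p = 0.0176, Fisher exact): *BomS2* (−2.70 ± 0.23), *BomS6* (−3.53), *BomS3* (−2.81) and *BomS1* (−2.08). The actin family fell in 4 of 6 members, *Act57B*, *Act87E*, *Act88F* and *Act42A*, the last from 2452 and 2352 CPM to 1083 and 1318 CPM, while *Act5C* had a log2 fold change of −0.25 and was not called. The *Jon* proteases rose in 15 of 15 members (adjusted p = 3.85e-13, Fisher exact) and the maltase-led *Mal* family in 6 of 9 (0.00506), with 1 fall, *Mal-A5* (−0.59 ± 0.13), from 235 and 233 CPM to 164 and 147 CPM. The *Cp* prefix, with 6 rises among 11 members (0.0176), mixes chorion genes with the centrosomal genes *Cp110* and *Cp190*. The cuticle family *Cpr*, with 5 falls among 13 members, failed the adjustment (adjusted p = 0.0676).

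Most digestive transcripts were higher in both libraries labelled *Nipped-A* RNAi, and levels were higher in library 2 than in library 1 for 43 of 45 further gut genes. Of these 45 genes, picked by family name or known gut role, 73.3% (33) were called higher and *Mal-A5* lower; the bound set for gut tissue carried over at dissection was 75%, which the share meets (33 of 44, or 75%) once *LysRS*, a tRNA synthetase taken in by the name rule for lysozymes, is left out, so that this outcome rests on 1 gene. Carried-over gut and gut genes switched on in ovarian cells cannot be told apart, since both raise these genes. *Bace* was the most abundant of them, at 0.543 and 1.83 CPM against 332 and 1443 CPM, *tobi* had 8.83 and 8.69 against 193 and 313 CPM, and 13 of the 45 had a mean of at least 1 CPM in the libraries labelled *bam* RNAi. Reads shared among near-identical copies as the whole source are argued against by the 15 genes outside the large families, of which 66.7% were called higher. Some of the 15, such as *PGRP-SC2*, *Acbp3* and *Acbp5*, have relatives of their own, so they are not a set free of paralogs.

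*Nipped-A* was higher, not lower, in the libraries labelled as its knockdown. With the trend with gene length removed, its log2 fold change went from 0.70 to 0.31 and was no longer called (edgeR, Benjamini-Hochberg adjusted p = 0.130). The range at 2 SE stayed above 0 (0.08 to 0.54), which met the bound set against length as the source. That range leaves out the error of the fitted trend, and upper-quartile scaling, which alone gave 0.49, was not combined with the removal. Length as the whole source is therefore not excluded. The nosGAL4 driver is not active in muscle sheath, cap and escort cells, whose pooled markers had a median of −0.73 (quartiles −1.43 and −0.23, 29 genes). A larger share of muscle sheath cells is argued against by their own markers, with a median of −1.43 and 11 of 15 called lower. The cap and escort genes alone had a median of −0.32 and an upper quartile of −0.06, with 1 of 14 called. Those values are too small to decide on cap and escort cells. A larger share of follicle or gut cells, whose lists had medians of 0.48 and 8.89, stays open. An exchange of labels between the groups stays open, since *bam* at 2.03 goes with its own label, while the series title has the Tip60 complex promote a differentiation factor without naming it; if that factor is *bam*, a *Nipped-A* knockdown could lower it as well. Reads from the hairpin itself, which gene counts without read positions cannot set apart, a knockdown acting on protein more than on transcript level, and a difference in germ cell stages stay open as untested.

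The lists of cytoplasmic ribosomal proteins, oxidative phosphorylation, mitochondrial ribosomal proteins and proteasome had medians of −0.79, −0.89, −0.58 and −0.40 in the libraries labelled *Nipped-A* RNAi, with 65 of 83, 49 of 66, 12 of 70 and 2 of 37 genes called lower and adjusted p = 0.812 for each with an estimated correlation. The trend with gene length is part of this. With it removed the median of the first pair of lists was −0.47 (quartiles −0.60 and −0.27, 149 genes), with 23 and 27 genes still called lower. These values argue against length as the whole source for the first pair. The median of the second pair was −0.19 (quartiles −0.30 and −0.05, 107 genes), with 1 gene called lower in each list. Both pairs met the bound set against length, but the quartiles leave out the error of the fitted trend. The small values of the second pair therefore do not exclude length as its whole source. The choice of scaling factors could not be tested this way: a factor shifts every gene alike, so the distance of the closest list median from that of all genes, −0.40 over 3 other scalings, is fixed by construction. What produces the length trend itself was not tested, and it also separates the *bam* RNAi libraries from one another. A difference in the germ cell stages present, which the genotypes could bring, stays open as an untested biological explanation.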
